A study of Homo sapiens with 2 samples.

How the data were processed

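The series holds 2 RNA-seq libraries of human naive CD4 T cells. Per the labels' protocols, CD4-positive, CD45RA-positive cells were isolated with a kit from blood mononuclear cells and cultured with CD3/CD28 beads, TGF-β at 10 ng/mL and IL-2 at 10 U/mL, with CPI-703 at 4 µM or with DMSO, and RNA was taken after 4 days. The titles and sample characteristics give the dose in µM; a protocol text prints the same figure in mM, and the µM unit was used. CPI-703 is known as an inhibitor of the CBP and EP300 bromodomains. The labels do not say whether both cultures came from the same cells. Read length, strandedness and annotation are not given in the sources used here.

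Per the submitters' processing notes the tools were TopHat 1.4.1 and Cufflinks, whose version is not given there, and the genome build was hg19. The authors deposited 1 table of FPKM per gene for both libraries. The table's name speaks of log2 values, but the deposited FPKM are on the linear scale: they start at 0 and reach 3853, and each library sums to about the same total, 424227 FPKM with CPI-703 and 424201 with DMSO. No counts were in the files used, so no count model was applied. The table lists 23073 gene IDs with symbols, of which 30 symbols read as spreadsheet dates. For 3 genes the DMSO value was missing (PAICS, KDM1A and NCAPG2) and these were left out. A further 465 IDs that can describe the donor (such as variable segments of immunoglobulins and T cell receptors) were left out of every comparison, list and named gene, leaving 22605. Totals per library (FPKM sums and numbers of IDs with FPKM of at least 1) cover the whole table. Starts in the table count from 0, as 13379 gene spans equalled those of GENCODE 29 read that way and 384 read from 1, so 1 was added to each start printed. Coordinates are those of the table in hg19. GENCODE 29, which is on GRCh38, served for transcript lengths, GC content and gene class, matched by Ensembl ID for 19827 IDs, and none of its coordinates is printed.

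Depth is not given, and was estimated from the FPKM. For the 2206 genes with a single GENCODE 29 transcript, FPKM times length in kilobases clusters at multiples of what 1 read is worth. That worth was 0.0499 FPKM-kilobase with CPI-703 and 0.0263 with DMSO, or 20.02 and 38.0 reads per FPKM and kilobase. Of low values (0.5 to 10.5 reads), 73.4% and 72.6% lay within 0.1 of a whole read, where evenly spread values would give 20%. The worth of 1 read was taken from the densest cluster of these same genes, which held 99 and 105 genes. Those lie near a whole read by selection, so 20% is not the chance level of this check. By the worth of 1 read, the CPI-703 library had 52.7% of the depth of the DMSO library. Whole reads could not be recovered for genes with several transcripts, so no interval is given for single genes. An exact 0 can be a failed estimate, since the 13 mitochondrial genes are at 0 in both libraries; such values are called listed at 0. The 10 most abundant genes held 4.15% of FPKM with CPI-703 and 3.51% with DMSO.

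The comparison was CPI-703 against DMSO. With 1 library per group no test was run. The difference was that of log2(FPKM + 1), CPI-703 minus DMSO, over genes with FPKM of at least 1 in at least 1 library, and genes were counted at 2-fold or more (log2 difference of 1). The pseudocount understates the fold of low genes. A gene list stood apart when its median difference lay below percentile 2.5 or above percentile 97.5 of the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. About 5% of lists of randomly drawn genes do so by chance, and the percentile describes these 2 libraries, not the treatment in general. The 36 lists (25 of T cell states and pathways, 1 of T cell identity, 5 of other cell types and 5 of quality), the size rule, the percentile rule and the alternatives not listed as later additions were fixed before the data were examined.

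Named genes followed a rule. It takes 12 genes in every case (CREBBP, EP300, FOXP3, IL2RA, CTLA4, LAG3, HAVCR2, TIGIT, PDCD1, IL10, IFNG and MYC), the 12 largest differences in each direction among genes with at least 5 FPKM in a library, and up to 4 members per list with the largest absolute difference. The rule took protein-coding genes only where the files give a class, which they do not, so all classes entered. It gave 141 genes, some of which are not reported here. Outside it and chosen after their values were seen are TNFRSF9, BST2, IRF7, TBX21, GATA3, SRGN, CISH, NR4A1, CD8A, CD8B, GAPDH, LDHA, TCF7 and LEF1. So are the marker genes LYZ, TYROBP, KLRD1, KLRF1 and GNLY of the closing section, and the genes that section names as chosen in this way. Genes with near-identical copies, overlapping genes and read-through genes are uncertain, because how shared reads were assigned is not given.

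Alternatives were pseudocounts of 0.1 and 0, no FPKM filter, a filter of 5, centring on the median of genes with FPKM of at least 10 in both libraries, rescaling each library to TPM, in which all libraries have the same total, 10 bins for the random lists and a 4-fold rule. The one with no pseudocount was planned on deposited log2 values and was computed from the linear FPKM. Chosen after seeing the data were removal of a cubic trend on transcript length and GC content, protein-coding genes by GENCODE 29, a filter of 10, and a filter of at least 1 on the mean FPKM of both libraries. On simulated reads for 11221 genes of this comparison, 91.5% of 200 genes raised by a log2 change of 1.5 and 92.5% of 200 lowered by 1.5 were found by the size rule. Among the genes not changed in those simulations, 5 and 1 came out at least 2-fold higher and 4 and 1 at least 2-fold lower from counting noise. Of 200 random lists of 20 genes 3.5% stood apart, and all did after a shift of −0.3. The depth estimate returned 20 and 40 reads per FPKM and kilobase, the values simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.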

Results

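RNA was sequenced from human naive CD4 T cells (CD45RA-positive) that had been stimulated through CD3 and CD28 and cultured for 4 days with TGF-β and IL-2, conditions that drive naive cells toward a regulatory T cell (Treg) state. One culture received CPI-703, an inhibitor of the bromodomains of the paralogous acetyltransferases CBP (CREBBP) and p300 (EP300), at 4 µM, and the other received the solvent DMSO. Each group held 1 library, so no difference below has a replicate check, no test was run and no p-value is given. Values are FPKM (fragments per kilobase of transcript, scaled to the number of mapped reads). The low values of both libraries lay at multiples of what 1 read is worth, and from these steps the CPI-703 library held 20.02 reads per FPKM and kilobase and the DMSO library 38.0. FPKM of at least 1 was listed for 11223 gene IDs in the CPI-703 library and for 11315 in the DMSO library. The comparison addressed which transcripts differed when the CBP and EP300 bromodomains were inhibited during Treg differentiation.

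Expression in the CPI-703 library was lower for interferon-stimulated genes, inhibitory receptors, helper and cytotoxic effector genes, and hypoxia and unfolded protein response genes, and few genes were higher. Of 11369 genes with FPKM of at least 1 in a library, 111 were at least 2-fold lower and 12 at least 2-fold higher in the CPI-703 library on the log2(FPKM + 1) scale, and the other 11246 (98.9%) lay within 2-fold. Folds named as passing or not passing a size are on this scale throughout, which understates the ratio of the FPKM themselves, most of all for low genes. The interferon-induced GTPase gene MX1 had the lowest difference, at 1.35 FPKM with CPI-703 and 9.64 with DMSO (log2 difference −2.18). It was followed by CST7, which encodes the protease inhibitor cystatin F (5.06 against 25.9 FPKM), and by the interferon-induced exonuclease gene ISG20 (9.32 against 43.8), and these 3 were the only genes at least 4-fold lower on this scale. No gene was at least 4-fold higher. Over all genes the median log2 difference was −0.02, and the central 95% of genes lay between −0.73 and 0.41. Across genes, which are not independent replicates, the libraries correlated with Pearson's r of 0.987 and Spearman's rho of 0.988. The counts depend on the pseudocount: 251 genes were lower and 38 higher with a pseudocount of 0.1. They also include read-through genes, T cell receptor joining segments and some genes listed at or just above 0 in 1 library, which may be failed estimates.

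**Figure D1:**
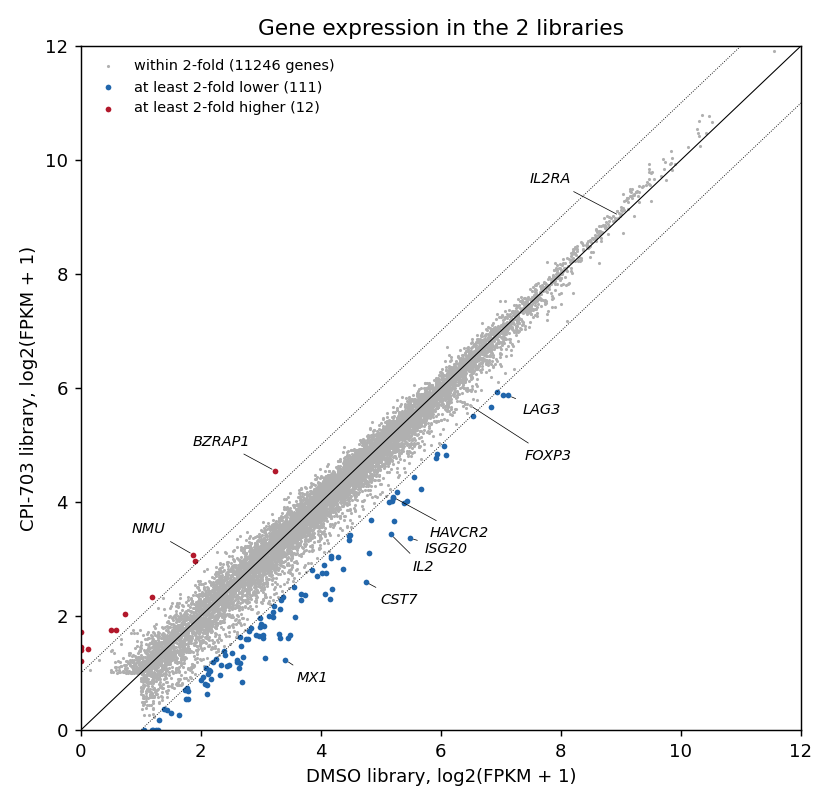
Each point is 1 of 11369 genes, placed by log2(FPKM + 1) in the DMSO library (x axis) and in the CPI-703 library (y axis). The solid line marks equal values and the dotted lines 2-fold differences; 111 genes lie on or below the lower dotted line and 12 on or above the upper one.

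FOXP3, the lineage-defining transcription factor gene of Treg cells (ENSG00000049768, chromosome X, 49106897 to 49121288, hg19), was listed at 50.8 FPKM in the CPI-703 library and 88.7 in the DMSO library, a log2 difference of −0.79, which does not reach 2-fold. IL2RA, the high-affinity IL-2 receptor chain gene, was nearly equal at 519 and 505 FPKM. The Treg list as a whole did not stand apart: its 24 measured members had a median of −0.06, 15 of them below 0, and the median lay at percentile 26.3 of 10000 random lists matched on expression. Members went both ways, with BATF at 25.7 against 41.0 FPKM and TNFRSF9 (4-1BB) at 183 against 126, and the mean difference was −0.17. With no FPKM filter the median over all 31 members was −0.07 (percentile 5.75), with 21 below 0 and 10 above. IL10 was near the floor in both libraries, at 0.031 and 0.048 FPKM. The genes of the inhibitor's targets were close to equal, CREBBP at 5.94 against 5.08 FPKM and EP300 at 8.17 against 8.37. Their list of 27 acetyltransferase, deacetylase and bromodomain genes had a median of −0.01 at percentile 60.5, with a mean of 0.02.

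Inhibitory receptors and ligands were lower together. All 13 measured members lay below 0, with a median of −0.41, and none of the random lists had a median as low. With no FPKM filter the median over all 15 was −0.25 (percentile 0.11). LAG3, an inhibitory receptor that binds MHC class II (ENSG00000089692, chromosome 12, 6881678 to 6887621), was at 57.5 FPKM with CPI-703 and 138 with DMSO, and HAVCR2 (TIM-3) was at 16.0 against 36.0. CD160 was the third member at least 2-fold lower, at 0.559 against 3.29 FPKM. The other 10 lay within 2-fold, among them BTLA at 16.0 against 28.1 FPKM, TIGIT at 3.94 against 7.18, CTLA4 at 58.3 against 77.9 and PDCD1 (PD-1) at 49.8 against 51.9.

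**Figure D2:**
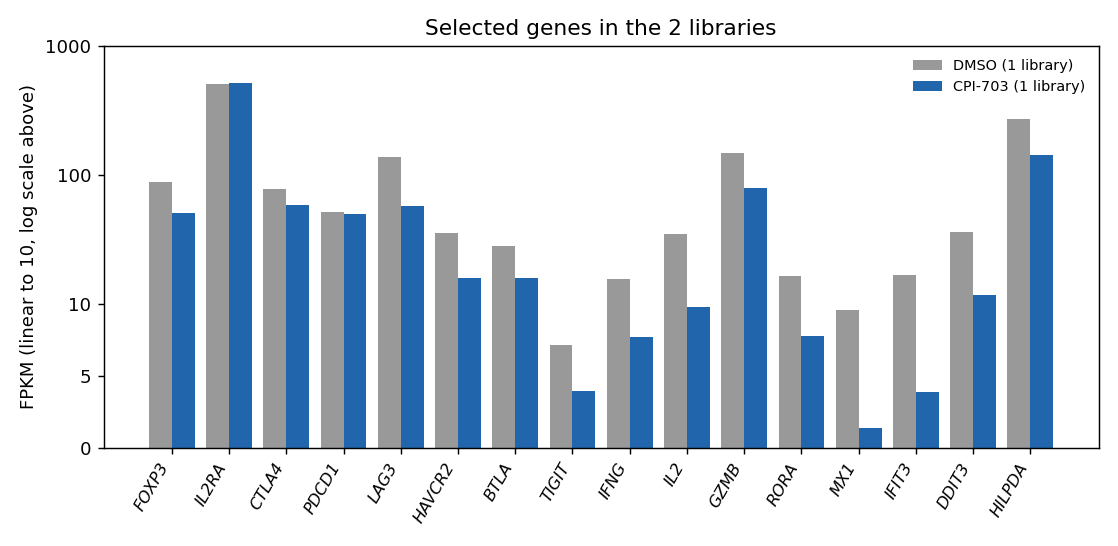
Bars give FPKM in the DMSO library (grey) and the CPI-703 library (blue), 1 library each and therefore without error bars, on an axis that is linear up to 10 and logarithmic above. FOXP3, LAG3 and HAVCR2 are lower in the CPI-703 library, and IL2RA and PDCD1 are close to equal.

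Interferon-stimulated genes had the lowest median of the main lists, at −0.83. Of 30 measured members, 28 lay below 0 and 12 were at least 2-fold lower, and none of the random lists had a median as low. IFIT3, an interferon-induced antiviral gene, was at 3.92 against 16.8 FPKM, IFI44L at 2.07 against 9.94, OASL at 1.41 against 7.45, and IRF7, a transcription factor of the interferon response, at 5.75 against 15.2. Of the members that did not follow, the antiviral gene BST2 was at 84.4 against 83.7 FPKM. The list of interferon-γ and antigen presentation genes did not follow. Its 19 measured members had a median of 0.08 at percentile 95.7, none was 2-fold different, and B2M, the common light chain of MHC class I, was at 3853 against 3003 FPKM, NLRC5 at 38.4 against 27.2 and TAP2 at 37.1 against 28.3. This list stood apart as higher in the absence of the FPKM filter (0.078) and after a trend on transcript length and GC content was removed (0.11).

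Genes of several helper T cell programmes were lower. The Th17 list had a median of −0.76 over 9 measured members, none of the random lists being as low, with IL23R at 0.137 against 1.46 FPKM, CCR6 at 0.637 against 2.35 and the transcription factor gene RORA at 7.79 against 16.6. On the log2(FPKM + 1) scale IL23R and CCR6 were the members at least 2-fold lower, and RORA, at −0.999, lay just short of it. IL23R and CCR6 had low FPKM and reached 1 FPKM in the DMSO library only. With no FPKM filter the median over all 15 members was −0.35, and again none of the random lists was as low. The Tfh list had a median of −0.62, with 10 of 11 members below 0. None was 2-fold different on the log2(FPKM + 1) scale, where the largest difference was −0.84 for CXCL13, at 0.291 against 1.31 FPKM, and with a pseudocount of 0.1 this difference was −1.85. ASCL2, a Tfh transcription factor gene, was at 1.02 against 2.601 FPKM. CXCR5, the receptor that guides cells to B cell follicles, was at 2.65 against 5.05 FPKM. For the Th1 list the median was −0.20 (percentile 0.52), IFNG being at 7.75 against 15.6 FPKM while TBX21, the Th1 master regulator gene, was at 14.5 against 13.1. Its 2 members that were at least 2-fold lower, the chemokine genes CCL3 and CCL4, have near-identical copies in the genome and are uncertain. The Th2 list did not stand apart (5 measured members, median 0.04, mean −0.17, percentile 69.8), GATA3 being at 24.2 against 23.6 FPKM and MAF at 5.10 against 10.7.

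Secreted cytokine genes had a median of −0.31 and chemokines and chemokine receptors one of −0.64, and none of the random lists was as low as either. Of the 22 cytokine genes measured, 19 lay below 0 and 2 were at least 2-fold lower on the log2(FPKM + 1) scale: IL2, the T cell growth factor gene (ENSG00000109471, chromosome 4, 123372625 to 123377880), at 9.81 against 35.0 FPKM, and IL24 at 1.38 against 3.77. Of 14 chemokine and receptor genes 13 lay below 0, and 3 were at least 2-fold lower on that scale: CCL3, CCL4 and CCR6. CCL3 and CCL4 have near-identical copies and are uncertain, and CCR6 reached 1 FPKM in the DMSO library only. With no FPKM filter the median over all 28 chemokine and receptor genes was −0.18, also lower than in any random list. IL-2 and STAT5 response genes had a median of −0.24, lower than in any random list, with 13 of 20 members below 0 and 7 above. CCND2 (cyclin D2) was at 50.4 against 81.3 FPKM and the kinase gene PIM1 at 47.0 against 74.0, whereas the STAT5 target gene CISH was at 123.2 against 107. T cell receptor early response genes had a median of −0.13 (percentile 0.96), with 13 of 22 below 0 and 9 above. Among these ATF3 was at 30.7 against 65.4 FPKM and RGS1 at 16.3 against 33.0, whereas the nuclear receptor gene NR4A1 was at 94.2 against 69.1. Naive and recirculation genes had a median of −0.18 (percentile 0.32), with 12 of 16 members below 0 and 4 above. The costimulatory receptor gene CD28 was at 51.8 against 85.2 FPKM, whereas TCF7 was at 35.2 against 27.6 and LEF1 at 175 against 168. NF-κB targets did not stand apart (median −0.11, percentile 3.83), with TNFAIP3 at 76.1 against 133 FPKM and CD83 at 104 against 67.6, nor did TGF-β response genes (median 0.02, mean −0.02, percentile 80.1), with TGIF1 at 38.5 against 54.6 and SMAD3 at 5.17 against 3.92.

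Cytotoxic granule genes had a median of −0.48 (percentile 0.02). The serine protease gene GZMB was at 79.3 FPKM with CPI-703 and 148 with DMSO, GZMH at 6.63 against 13.2 and NKG7 at 4.06 against 9.31, and only NKG7 was at least 2-fold lower. All 7 measured members lay below 0, but SRGN, at 254 FPKM in both libraries, lay above 0 when the median difference was set to 0 and 1 member did so when the length and GC trend was removed. GZMB and GZMH are similar in sequence and may share reads. Markers of CD8 T and NK cells were also lower, with a median of −1.13 over the 4 of 13 that were measured (percentile 0.01): NKG7, SPON2 at 0.748 against 3.22 FPKM, FGFBP2 at 0.470 against 2.46 and NCR3 at 5.84 against 12.4. SPON2 and FGFBP2 reached 1 FPKM in the DMSO library only, and with no FPKM filter the median over all 13 markers was −0.22 (percentile 0.38). Summed CD8A and CD8B FPKM was 0.988 with CPI-703 and 0.771 with DMSO. The T cell identity list did not stand apart (15 members, median −0.01, percentile 30.9). Markers of B and plasma cells (2 measured, median −0.22, percentile 17.7), monocytes and dendritic cells (3 measured, median −0.40, percentile 5.0) and γδ T and MAIT cells (2 measured, median −0.10, percentile 37.4) did not stand apart, and no erythroid or platelet marker reached 1 FPKM.

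Hypoxia response genes were lower, with a median of −0.57 and 20 of 21 measured members below 0. The peptide hormone gene ADM was at 2.20 against 10.2 FPKM, the oxygen-sensing hydroxylase gene EGLN3 at 4.22 against 11.7 and the MYC antagonist gene MXI1 at 27.6 against 60.6, and these were the 3 members at least 2-fold lower. HILPDA, a lipid droplet protein gene, was at 144 against 274. ATF4 and unfolded protein response genes had a median of −0.50, with 21 of 24 members below 0, and the stress transcription factor gene DDIT3 (CHOP) was at 11.8 against 36.2 FPKM, CHAC1 at 2.06 against 7.26 and the chaperone gene DNAJB9 at 5.78 against 16.0. Apoptosis regulators had a median of −0.29, PMAIP1 (NOXA) being at 54.1 against 96.1 FPKM and the anti-apoptotic BCL2 at 22.9 against 35.0. None of the random lists was as low as any of these 3 lists. Glycolysis genes had a median of −0.12 (percentile 0.545), with 16 of 21 members below 0, 5 above and none 2-fold different. PFKFB4 was at 18.6 against 33.7 FPKM and SLC2A3 (GLUT3) at 85.2 against 118. The enzyme genes GAPDH, at 1374 against 1255, and LDHA, at 980 against 951, were slightly higher.

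Cell cycle, growth and sterol lists did not stand apart. Cell cycle genes had a median of 0.01 over 40 members (percentile 67.8), the largest member difference being that of CCNE1 (cyclin E1) at 29.7 against 22.6 FPKM. MYC and ribosome biogenesis genes had a median of 0.06 (percentile 95.4) and stood apart as higher once the length and GC trend was removed (0.071), whereas MYC itself was at 87.7 against 121 FPKM. Cholesterol biosynthesis genes had a median of −0.03 (percentile 33.3), with HMGCS1 at 48.2 against 67.98 FPKM, and p53 targets one of −0.03 (percentile 42.7), with FAS at 28.7 against 43.1. Ribosomal protein genes were the only list that stood apart as higher: 42 of 44 lay above 0, with a median of 0.17, above every random list, and RPS23 was at 703 against 571 FPKM. Commonly used reference genes had a median of 0.10 (percentile 97.1), ACTB being at 1778 against 1308 FPKM. Stress genes linked to cell handling had a median of −0.03 (percentile 37.3). Replication-dependent histone genes had a median of −0.50 (percentile 1.01) over the 6 of 16 that were measured, all in near-identical families. It was −0.15 over all 16 with no filter and −0.93 with a pseudocount of 0.1, and stood apart in both, but not at a filter of 5 FPKM, where 2 members were left (−0.75, percentile 6.16). The 13 mitochondrially encoded genes were listed at 0 in both libraries.

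**Figure D3:**
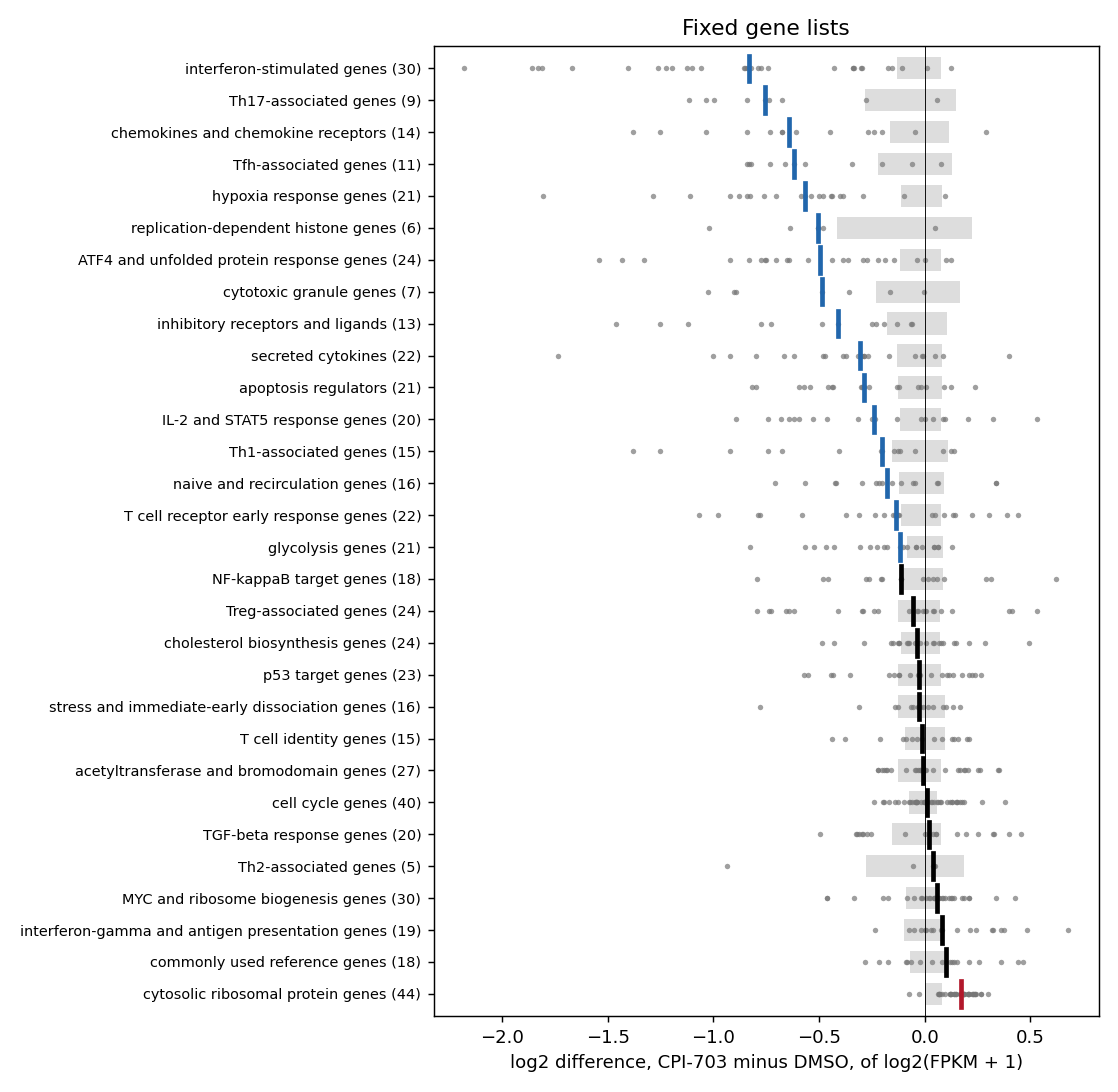
Each row is a fixed gene list with at least 5 measured members (number in brackets). Grey points are members, placed by the difference of log2(FPKM + 1), CPI-703 minus DMSO. The thick line is the list median, blue where it stood apart as lower, red where higher and black where it did not, and the grey box spans the central 95% of medians of 10000 expression-matched random lists. Interferon-stimulated genes lie lowest, at −0.83, and ribosomal protein genes highest, at 0.17.

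In all, 17 of 34 measured lists stood apart as lower and 1 as higher, where about 1.7 would among lists of randomly drawn genes. Genes of a list can differ together between any 2 cultures, so this excess does not separate the compound from a culture difference. Of the 677 list members 70 were in more than 1 list, but unevenly. Shared members were 20 of 34 secreted cytokine genes, 11 of 20 IL-2 and STAT5 response genes and 10 of 15 Th17 genes. They were 1 of 30 interferon-stimulated genes and, in a list that did not stand apart, 12 of 31 Treg genes. The lists that stood apart are therefore not all separate results. Of the 111 lower genes 32 belonged to a fixed list. Among the largest differences outside the lists were DOK5, an adaptor of receptor tyrosine kinases, at 2.08 against 9.03 FPKM, NAPSA, an aspartic protease gene, at 4.60 against 17.2, and PPP1R15A (GADD34), a phosphatase subunit gene that acts in the integrated stress response, at 7.64 against 26.8. TRAJ48, a T cell receptor joining segment of 63 nucleotides, was also among the 12 largest lower differences, at 0.793 against 5.43 FPKM, but FPKM of so short a feature rests on few reads. In the other direction BZRAP1 (ENSG00000005379, chromosome 17, 56378592 to 56406152) was at 22.4 FPKM with CPI-703 and 8.46 with DMSO, the neuropeptide gene NMU at 7.44 against 2.68, and CARD16 at 6.87 against 2.75. CARD16 shares sequence with CASP1 and is uncertain. These were the 3 genes at least 2-fold higher with at least 5 FPKM in a library. The next by size, within 2-fold on the log2(FPKM + 1) scale, were OSBPL7 at 7.72 against 3.85, ABCC10 at 9.28 against 5.06, DHRS11 at 5.91 against 3.16 and TMEM91 at 6.12 against 3.29. IFFO1, ARHGAP33, HLA-DMB, MRC2 and LIG3 completed the 12, with log2 differences from 0.72 down to 0.67. The other 9 genes at least 2-fold higher included 4 T cell receptor joining segments, and some of the rest were listed just above 0 in the DMSO library.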

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

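Of these alternatives, removal of the length and GC trend, the GENCODE 29 class, the filter of 10 FPKM and that on the mean FPKM were chosen after the data were seen. Genes stayed more often lower than higher under every alternative, but their number followed the pseudocount and the filter. At least 2-fold lower and higher were 251 and 38 genes with a pseudocount of 0.1, 268 and 42 with none, 175 and 25 after rescaling to TPM, 45 and 1 at an FPKM filter of 10, and 3 and 0 under the 4-fold rule. Only the number higher moved by over 1.5 times with a filter of 5 FPKM (3, with 77 lower) and among protein-coding genes (7, with 103 lower). Such filters can only remove genes, in either direction. Both libraries have nearly the same FPKM sum, so rescaling to TPM acts as a smaller pseudocount, and neither it nor a pseudocount of 0.1 can remove a lower gene. With none, 110 of the 111 lower genes remained, since TRAJ16, listed at 0 with CPI-703, has no ratio. Of the 111 lower genes 103 remained after centring and 105 after the length and GC trend was removed. The list of interferon-γ and antigen presentation genes stood apart as higher with no filter (median 0.078) and with the length and GC trend removed (0.11), as did MYC and ribosome biogenesis genes with that trend removed (0.071); the cause was not tested. No list median that stood apart changed sign with no filter or with the length and GC trend removed. With no filter, list medians moved by over 1.5 times toward 0 for 5 of the lists that stood apart, whose values stand in the report, since members near 0 FPKM enter. A filter on the mean of both libraries, which does not favour genes that are lower, left 8 genes higher and 103 lower, and all 34 lists on the same side of the threshold. Among lists outside the main ones, histone genes no longer stood apart at a filter of 5, where 2 were left, and reference genes did so with no filter and with 10 bins. Of the named genes 13 moved by over 1.5 times with no pseudocount, 8 with 0.1 and 1 (IL23R, log2 difference −1.75) after rescaling. No paired analysis was possible because each group has 1 library, and for the same reason no library could be left out. The planned restriction to protein-coding genes by the files' own class was not run, since they give none. Depth limits low genes most, and the shallower library was the CPI-703 one.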

Other observations

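Genes of this and the next paragraph lie outside the lists and were chosen after their values were seen. Several receptors and signalling genes of T cells were at least 2-fold lower in the CPI-703 library: CD226, a costimulatory receptor that shares ligands with TIGIT, was at 15.3 FPKM against 35.5 with DMSO, the oxysterol receptor gene GPR183 at 20.6 against 45.9, AMICA1, an adhesion molecule gene, at 57.9 against 130 and the signalling inhibitor gene SPRY1 at 14.7 against 40.6. The transcriptional repressor gene ZBTB32 was at 59.9 against 122 FPKM and INSIG2, a regulator of sterol synthesis, at 44.8 against 91.4. Of 6 measured metallothionein genes, which encode metal-binding proteins, all had differences below 0 and MT3 alone was at least 2-fold lower on the log2(FPKM + 1) scale, at 17.7 against 49.6 FPKM. MT1G was at 1.85 against 4.59 FPKM (log2 difference −0.97), MT2A at 23.1 against 40.8 and MT1X at 13.1 against 15.0. The family was not set against random lists, and its members are similar in sequence and may share reads. Fibronectin (FN1), at 3.10 against 0.663 FPKM, was among the 12 genes at least 2-fold higher.

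Transcripts of some interferons were seen at low levels. IFNB1 was listed at 0 with CPI-703 and at 0.595 FPKM with DMSO, and IFNL1 was at 0.058 against 0.522. In the DMSO library, where 3 reads of either gene are worth 0.092 FPKM, these values correspond to about 19.4 and 17 reads. In the CPI-703 library IFNL1 corresponds to 1 read, below the 0.175 FPKM that 3 reads of it are worth there. The transcripts of the receptor chains and kinases that carry the interferon signal were present at similar levels, with IFNAR1 at 35.2 against 38.8 FPKM, IFNAR2 at 56.7 against 59.6, JAK1 at 42.4 against 37.9 and TYK2 at 39.6 against 37.1.

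In the patterns weighed next, the tests of length and GC bias were set out before their results were seen, and all others after. The first pattern is that 111 genes were at least 2-fold lower and 12 higher. Unequal depth as the whole cause is argued against by genes with at least 10 FPKM in a library, of which 45 were lower and 1 higher. A trend on length and GC content as taken here does not account for the pattern, since 114 genes were lower and 12 higher after its removal. Both properties were known for 96.4% of the lower genes. Across genes the difference had a Spearman rho of 0.195 with GC content and −0.027 with length. Length was the median over a gene's annotated transcripts, which short ones can lower (CREBBP 535.5 and EP300 492 nucleotides). Bias by the length of the transcripts expressed was therefore not tested and stays open. A difference between the cultures other than the compound cannot be told apart from its effect, because there was 1 library per group. Inhibition of the CBP and EP300 bromodomains, which the design names, stays among the open explanations.

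The second pattern is the lower level of interferon-stimulated genes. Their median was −0.81 after the length and GC trend was removed, and transcripts lost with myeloid cells as the whole cause are argued against by LYZ and TYROBP, abundant in such cells but at most 0.101 FPKM with DMSO (TYROBP 0.241 with CPI-703), where the list summed to 173 FPKM less with CPI-703, although ITGAM (0.495 against 1.28), CD68 (4.17 against 5.72) and AIF1 (20.9 against 27.9) were lower too. The antigen presentation list did not share the fall, and its median lay 0.913 above that of the interferon-stimulated list. The same gap between 10000 pairs of random lists was at most 0.329. Both medians were known when this comparison was set out, so its outcome was fixed and decides nothing further. A fall of equal size in both lists was not seen, but a weaker interferon signal stays open. A lower level of interferon transcripts may be a candidate explanation for part of the list. IFNB1 was at 0.595 FPKM with DMSO, but a value listed at 0 in the CPI-703 library can be a failed estimate. IFNL1, not listed at 0, was at 0.058 FPKM with CPI-703 and 0.522 with DMSO, or 1 and 17 estimated reads. So few reads, in 1 library per group, leave this explanation open. The effect of the inhibitor on the genes themselves and a difference between the cultures also stay open.

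The third pattern is the lower level of cytotoxic and NK-associated genes. Fewer NK cells remain possible. The highest of GNLY, KLRD1, KLRF1 and TYROBP was KLRD1 with 0.952 FPKM in the DMSO library. This was 10.2% of NKG7, just above the share set as the mark of this explanation. GNLY was at 0.180 FPKM with CPI-703 and 0.772 with DMSO, whereas TYROBP was higher with CPI-703. Values under 1 FPKM leave this open. Fewer CD8 T cells could not be decided either, as the sum of CD8A and CD8B was 1.28 times as high with CPI-703 but under 1 FPKM in both libraries. Isolation of CD4 T cells would remove most cells of both types, and activated CD4 T cells also express several of these genes. Whether the difference arose within CD4 T cells was not tested.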
